A study of Mus musculus with 52 samples.

How the data were processed

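RNA was measured in B cells from lymph nodes of mice with lymphomas driven by the Eµ-myc transgene, in 52 libraries of ribosome-depleted total RNA. The labels define 10 groups. In 4 tumours (T1 to T4) with a p53 allele that 4-hydroxytamoxifen (OHT) switches on, cells were given ethanol or 100 nM OHT for 2 h. In 3 tumours lacking Arf and carrying intact p53 (T5 to T7), cells were given water, 1 µM doxorubicin, 5 µM (+)-Nutlin or 5 µM (-)-Nutlin for 3 h, and the same treatments were given to T5 to T7 infected with a short hairpin RNA against p53 (shp53). The uninfected and OHT groups have 2 libraries per tumour, numbered rep1 and rep2, and each shp53 group has 1 library per tumour. The labels contain no infected control without the hairpin.

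The authors deposited 1 table of exonic RPKM (eRPKM, exonic reads per kilobase of exon, scaled to library size) for 21671 gene symbols. The submitters' processing notes name TopHat, TopHat2 2.0.8 and featureCounts 1.4.5 with build mm9, without their order. What reads the scaling counts, the annotation, the treatment of strand and of duplicate reads are not stated, so values of overlapping or antisense genes and of near-identical copies, such as the histone genes and the Hspa1a and Hspa1b pair, are uncertain. The table gives no coordinates. Of the symbols, 21594 matched a gene of the RefSeq table for GRCm38.p6, which was used to assign chromosomes.

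Read totals were not used here. A depth was estimated per library from the spacing of the lowest non-zero values, with exon lengths from GENCODE M21 found for 20793 symbols, and lay between 4.1 and 12.3 M reads in 51 libraries. The highest value of a library multiplied by that depth lay between 1442 and 2599 reads per kilobase in those 51, a narrow range for the depths seen, so values of the most abundant genes depended on depth. The shp53 libraries listed 645 to 4773 genes at 0, and the uninfected libraries of T5 to T7 listed 5285 to 7483. The lower quartile reached 1.15 eRPKM with shp53 and 0.025 eRPKM without, so low values lay higher with shp53. Whether this is background was not tested.

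The T1 ethanol rep1 library was truncated. It listed 4797 of 4800 expressed genes (5 eRPKM or more) on chromosomes 2 to 9, X and Y at 0, with 282 of 347 on chromosome 19 and 13 of 4271 on the others. The T2 ethanol rep1 library listed 284 of 284 expressed genes on X at 0. In the 50 other libraries at most 1.06% of expressed genes were at 0 on any chromosome other than Y, which was not counted. The first library was left out, and the X and Y values of the second were treated as missing, a departure from the design decided before any test. With all values as listed, the OHT comparison called 1 gene where 955 were called without them.

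The tumour was the biological replicate. Values were averaged over the libraries of a tumour and treatment after log2(eRPKM + 0.5). Genes with a mean of at least 1 eRPKM in a group were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. T1 to T4 were fitted with tumour as a term. The 8 groups of T5 to T7 were fitted together with a term per tumour and infection status. The comparison of shp53 with uninfected cells used a term per tumour, and the OHT and Nutlin responses were compared on differences per tumour. The former took the treatments of a tumour and infection status as separate replicates, with 14 residual degrees of freedom. Their values were correlated, so the SE and p-values of that comparison can be too small. Intervals are 95% intervals from the same models.

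The pairing by tumour rests on T1 to T7 in the sample titles, read here as the tumour of origin. The labels do not say in words that cells of a tumour were divided over the treatments. The pairing was checked by the correlation, over genes outside X and Y, of deviations from the group means. The correlation between ethanol and OHT lay at 0.786, 0.803, 0.721 and 0.728 for T1 to T4, with a median of -0.257 between tumours. The median correlation between treatments was 0.762, 0.757 and 0.712 for uninfected T5, T6 and T7 and 0.764, 0.799 and 0.547 with shp53. Between uninfected and shp53 libraries it was 0.489 for T5, 0.18 for T6 and -0.058 for T7. Among single libraries of T1 to T4, pairs from a tumour had a median of 0.77 with the same replicate number and 0.218 with the other number.

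Genes named for the comparisons and the 21 lists follow a rule fixed before the data were examined; Ddx3y, Xist and members of lists written later, among others, were chosen after the data were seen. Those under the rule are Trp53, Cdkn2a, Myc, Mdm2 and Cdkn1a; the 8 largest called rises and falls in the main comparisons (5 in the others) with the same direction in every tumour and a mean of at least 2 eRPKM in the higher group; and up to 4 members with the lowest p of each of 21 gene lists (372 genes). RNAs under 200 bases and unnamed gene models were passed over. For the difference of OHT and Nutlin responses, the same direction meant that the 4 OHT and 3 Nutlin responses did not overlap. Lists with at least 3 measured members were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the lists. Overlaps of calls were tested with the two-sided Fisher exact test.

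The steps were tested on simulated data with 200 genes changed. Noise was normal, independent between genes, and of 1 SD per gene in all samples. Correlated genes, a floor at 0 eRPKM and shp53 values from 1 library were not simulated, so the shares may not carry over to the real data. In the OHT comparison (11859 genes), 48.5% of changes of 0.5, 91% of changes of 1 and 95.5% of changes of 2 on the log2 scale were recovered, and 3.1% of calls were false. For doxorubicin (14637 genes) the shares were 34.8%, 79.1% and 98.5%, with 6.6% false calls. For (-)-Nutlin they were 40.9%, 77.6% and 95.5%, with 4% false. For the difference of doxorubicin responses they were 15.2%, 68.7% and 92.5%, with 6.3% false.

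Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter, a filter at 5 eRPKM, centring of libraries on their median, each tumour left out, fits without the tumour term, single libraries as replicates, and separate fits. Alternatives chosen after seeing the data were all values as listed, quantile normalisation, and T7 uninfected from rep2 libraries alone, together with the reruns of overlaps and list tests. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.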

Results

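Exonic RPKM of 21671 genes was measured in 52 libraries from 7 mouse B-cell lymphomas. Of these, 16 libraries came from the 4 tumours with OHT-switchable p53 (8 per group), 24 from the 3 uninfected Arf-deficient tumours (6 per group) and 12 from the same 3 tumours with shp53 (3 per group). Estimated depth was 4.1 to 12.3 M reads in 51 libraries and 2.5 M reads in the truncated T1 ethanol library, which was left out.

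The hairpin's target was lower in every infected library. Trp53, which encodes p53, lay between 15.1 and 38.8 eRPKM in the 12 shp53 libraries and between 40.85 and 89.1 eRPKM in the 24 uninfected libraries of T5 to T7. In water, Trp53 was 61.4 ± 10.2 eRPKM (SD, n = 3 tumours) without and 19 ± 3.45 eRPKM with the hairpin, a fall of log2 -1.65 (SE 0.12, adjusted p = 1.62e-06, 3 of 3 tumours). Cdkn2a, the locus that encodes Arf, was 56.4 ± 3.18 eRPKM in ethanol-treated T1 to T4 (n = 4) and 6.21 ± 8.30 eRPKM in water-treated T5 to T7 (n = 3), where T5 uninfected libraries held 10.7 to 22.2 eRPKM and T5 shp53 libraries 0.54 to 1.53 eRPKM.

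Libraries labelled T7 did not form a single set by sex-linked genes. Ddx3y, on chromosome Y of GRCm38.p6, was 41.0, 41.0 and 43.1 eRPKM in the T7 rep1 libraries with water, (+)-Nutlin and (-)-Nutlin, which also held Xist, the X-inactivation RNA, at 38.4, 37.1 and 28.5 eRPKM. The other 5 uninfected libraries labelled T7 held Ddx3y at 0.11 eRPKM or less and Xist at 73.8 to 98.8 eRPKM, and the T7 shp53 libraries held Ddx3y at 46.4 to 60.4 eRPKM and Xist at 0.18 to 0.54 eRPKM. The T7 rep1 doxorubicin library was among the 5, with Ddx3y at 0.07 and Xist at 98.82 eRPKM, unlike the T7 rep1 water library. The T7 doxorubicin response without shp53, and comparisons that use it, can therefore include a difference between these sets. For (-)-Nutlin against (+)-Nutlin both T7 rep1 libraries held Ddx3y. Labels were kept as given, and counts with T7 from rep2 libraries alone are given where they differ.

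**Figure D1:**
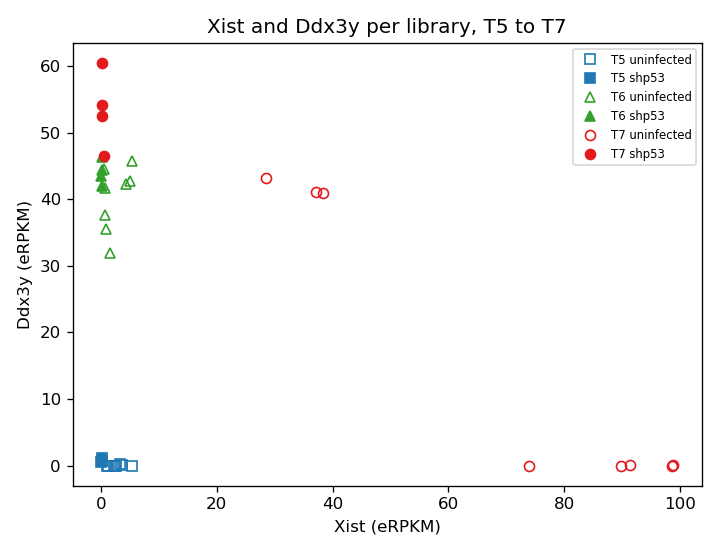
Xist against Ddx3y (eRPKM) per library of T5 to T7, open symbols uninfected and filled symbols shp53. The 3 T7 libraries with Ddx3y of 41.0 to 43.1 eRPKM lie apart from the other 5 uninfected T7 libraries.

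Restoring p53 with OHT for 2 h raised p53 target genes in all 4 tumours. Phlda3, a repressor of Akt signalling, rose by log2 4.75 (SE 0.22, adjusted p = 1.17e-07) from 1.16 ± 1.37 to 37.75 ± 18.8 eRPKM (SD, n = 4, with the T1 ethanol value from 1 library). Cdkn1a, the cyclin-dependent kinase inhibitor, rose by log2 3.86 (SE 0.27, adjusted p = 4.47e-06), and Mdm2, the ubiquitin ligase that targets p53, by log2 1.00 (SE 0.07, adjusted p = 4.75e-06). Fam131a (4.08), Zfp365 (3.00), Fam212b (2.91), the ephrin receptor gene Epha2 (2.75), Micall2 (2.51) and the costimulatory gene Cd80 (2.41) were the other largest rises on the log2 scale, each in 4 of 4 tumours. Fam131a, Zfp365 and Micall2 had ethanol means below the pseudocount, so their log2 changes depend on it. Falls were smaller, with Cybb, a subunit of the phagocyte oxidase, at log2 -0.85 (SE 0.17), Spink11 at -0.84, Spinkl at -0.63, Gas2l3 at -0.61, Cysltr1 at -0.61, Depdc1a at -0.50 and Ly6d at -0.48. Trp53 (0.04, interval -0.11 to 0.18), Cdkn2a (0.03) and Myc (0.10) did not pass the test.

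Among fixed lists, 9 of 13 measured p53 apoptosis genes rose with OHT, including Bbc3 by log2 2.28, Pidd1 by 1.10 and Bax by 0.67. In the p53 cell cycle and feedback list 9 of 14 rose and 1 fell, with Ccng1 at 1.19 and Gtse1 at 0.90. Of 18 metabolism and stress targets 7 rose and 1 fell, with Sesn2 at 1.37 and Ddit4 at 0.86, and of 19 immediate early genes 11 rose, with Ier3 at 1.59, Egr1 at 1.32 and Ier5 at 1.29. Adjusted camera p was 2.85e-11, 6.32e-12, 7.94e-05 and 6.32e-12 for these lists with the preset correlation, and adjusted p was 0.233, 0.332, 0.388 and 0.388 with an estimated correlation. The noncoding p53 list (3 of 4 rose, Pvt1 at 0.94), the heat shock list (2 of 9 rose), replication histones (5 of 46 rose, Hist2h2aa1 at 1.46) and the G2/M list (1 of 28 fell, Aurka at -0.25) had camera adjusted p of 0.0165, 0.00903, 9.43e-06 and 0.0013, and adjusted p of 0.388, 0.606, 0.636 and 0.635 with an estimated correlation. The other tested lists, among them DNA repair (adjusted p = 0.435), G1/S (0.714), NF-kB targets (0.463) and B lineage (0.952), were not called. Adjusted over the list alone, 9 of 13 apoptosis genes, 11 of 14 cell cycle and feedback targets and 13 of 19 immediate early genes rose. The fry test gave an adjusted p of 0.0193 and 0.0295 for the apoptosis and the cell cycle and feedback lists and 0.0834 for the immediate early list.

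The limma test called 955 of 11859 genes with OHT, 653 higher and 302 lower. The count was 28 without the tumour term (no replicate block), 2155 with single libraries in a replicate block, 43 without the filter, 489 without T4, 561 without T3 and 1564 without T2. With all values as listed, including the truncated library, 1 gene was called.

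Doxorubicin, a DNA-damaging drug, raised p53 targets in uninfected tumours. Cdkn1a rose by log2 3.68 (SE 0.37, adjusted p = 2.37e-06) from 7.54 ± 2.51 to 96.8 ± 14.3 eRPKM (SD, n = 3), and Mdm2 by log2 1.72 (SE 0.11, adjusted p = 5e-09). The largest rises were Fam131a (log2 4.90), Adm, which encodes adrenomedullin (4.72), Ier3 (4.55), Tnfaip3, an inhibitor of NF-kB signalling (3.95), Wnt10b (3.95), Micall2 (3.91), Tnfsf4 (3.86) and the sestrin gene Sesn2 (3.75), each in 3 of 3 tumours. Fam131a, Wnt10b, Micall2 and Tnfsf4 had water means below the pseudocount, so their log2 changes depend on it. The largest falls were B3gnt5 (-1.77), Serpinb1a (-1.74), Rnase12 (-1.70), the recombinase genes Rag2 (-1.57) and Rag1 (-1.54), the sphingosine receptor gene S1pr1 (-1.52), St8sia4 (-1.48) and Prr33 (-1.36). Trp53 was 0.31 higher on the log2 scale (adjusted p = 0.0505) and Myc 0.21 higher (adjusted p = 0.144), and neither passed the test.

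With doxorubicin, 12 of 15 p53 apoptosis genes rose and 1 fell (Bbc3 2.77, Pidd1 2.38, Tnfrsf10b 2.30), 13 of 14 cell cycle and feedback targets rose and 1 fell (Plk2 2.75, Gtse1 1.52), and 11 of 19 metabolism and stress targets rose and 2 fell (Dcxr 2.67, Ulk1 1.87). These lists were called with the preset correlation and with an estimated correlation (adjusted p = 0.00629 for each with an estimated correlation). In the DNA repair list Ercc5 (2.21) and Polk (1.72) rose, while Polh (-0.45) and Rrm2b (-0.81) fell, and the list was called by fry (adjusted p = 2.94e-05) but not by camera (adjusted p = 0.579). Of 16 NF-kB targets 11 rose, with Nfkb2 at 3.06, Cd40 at 3.03, Icam1 at 2.12 and Nfkbia at 1.70 (adjusted camera p = 6.2e-08, adjusted p = 0.141 with an estimated correlation). Of 19 immediate early genes 16 rose, with Jun at 3.34 and Nr4a1 at 1.69 (adjusted p = 6.04e-10, and adjusted p = 0.0985 with an estimated correlation). Of 28 G2/M genes 19 fell and 1 rose, with Ccnb1 at -0.91, Tpx2 at -0.73 and Cdk1 at -0.66 (adjusted p = 3.59e-07, and adjusted p = 0.212 with an estimated correlation). Myeloid markers were higher in 8 of 18 cases, with Cd68 at 0.82 and S100a8 at 1.37. The list had an adjusted camera p of 0.00394, and an adjusted p of 0.601 with an estimated correlation. Myeloid medians were 0.176, 0.354 and 1.627 in T5, T6 and T7, and 2 of 18 were higher when T7 was taken from rep2 libraries alone. Replication histones rose in 6 of 46 cases (adjusted p = 0.00921, and adjusted p = 0.824 with an estimated correlation). The heat shock (4 of 9 rose, 1 fell), B lineage (2 of 19 rose, 4 fell) and interferon lists (3 of 16 rose, 1 fell) were not called by camera. Nor were the lists of other BCL2 family genes (2 of 12 rose, 1 fell), noncoding p53 targets (3 of 6 rose, 1 fell), G1/S genes (5 of 27 rose, 5 fell), ribosome biogenesis genes (5 of 28 rose, 5 fell) and integrated stress response genes (4 of 14 rose, 3 fell). Of these, fry called the heat shock (adjusted p = 0.00251), noncoding p53 (2.74e-05) and integrated stress response lists (0.0107). The T cell (1 of 14 rose, 1 fell), erythroid (0 of 3) and stromal and endothelial lists (1 of 6 fell) were not called either, and NK markers (2 measured) were too few to test. Adjusted over the list alone, 12 of 15 apoptosis genes, 13 of 14 cell cycle and feedback targets, 12 of 16 NF-kB targets and 10 of 18 myeloid markers rose, and 20 of 28 G2/M genes fell.

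The limma test called 5710 of 14637 genes with doxorubicin, 2819 higher and 2891 lower; centring libraries on their median gave 2124 higher and 3781 lower, moving the median change of all genes from 0.029 to -0.087. The count was 2395 without the tumour term (no replicate block), 2588 without T5 and 2255 without T7.

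The Nutlin enantiomers were compared at the same dose and time. (-)-Nutlin, which blocks the binding of Mdm2 to p53, raised p53 targets relative to (+)-Nutlin, its far less active mirror image, in all 3 uninfected tumours. Cdkn1a rose by log2 2.78 (SE 0.37, adjusted p = 0.000226) from 8.85 ± 2.19 to 60.7 ± 5.23 eRPKM (SD, n = 3) and Mdm2 by log2 0.98 (SE 0.11, adjusted p = 2.26e-05). Myc was higher by log2 0.43 (SE 0.11, adjusted p = 0.0148), with 0.148, 0.376 and 0.777 in T5, T6 and T7. In T7 rep2 Myc was 210.78 eRPKM with (-)-Nutlin (4.1 M reads) and 88.5 eRPKM with (+)-Nutlin (11.2 M reads). In T7 rep1 it was 120.46 eRPKM (11.2 M reads) and 97.28 eRPKM (10.7 M reads), so the Myc change may depend on depth. The other largest rises were Micall2 (2.98), Phlda3 (2.91), Zfp365 (2.84), Fam131a (2.65), Fam212b (2.57), Tnfsf4 (2.56) and Cd80 (2.46). Micall2 and Tnfsf4 had (+)-Nutlin means below the pseudocount, so their log2 changes depend on it. Falls were Ak4 (-1.39), the sterol synthesis gene Msmo1 (-1.23), Tff2 (-1.17), Slurp1 (-1.09), the lactate transporter gene Slc16a3 (-1.08), Pmch (-1.08), Hsd17b7 (-0.998) and Coprs (-0.95). Trp53 was 0.04 higher (interval -0.22 to 0.30) and did not pass the test.

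With (-)-Nutlin, 12 of 15 p53 apoptosis genes (Bbc3 1.93, Pidd1 1.91) and 9 of 14 cell cycle and feedback targets (Plk2 1.92, Zmat3 1.51) rose, and 9 of 19 metabolism and stress targets rose and 1 fell (Ephx1 2.06, Sesn2 2.05). Their adjusted p was 0.00195, 0.00195 and 0.0122 with an estimated correlation. Of 19 immediate early genes 11 rose, with Jun at 2.15 and Egr1 at 1.79 (adjusted p = 1.09e-09, and adjusted p = 0.123 with an estimated correlation), and of 16 NF-kB targets 2 rose, Nfkbia at 0.56 and Ccl3 at 1.47 (adjusted p = 0.000537, and adjusted p = 0.372 with an estimated correlation). Replication histones rose in 16 of 46 cases (adjusted p = 4.03e-17, and adjusted p = 0.336 with an estimated correlation), with a median of 0.44 as deposited and 0.43 after quantile normalisation, which called 40. Myeloid markers rose in 8 of 18 cases, with C1qb at 1.71, Cd14 at 1.60 and C1qc at 1.47 (adjusted p = 2.54e-07, and adjusted p = 0.248 with an estimated correlation). T cell markers (0 of 14 called) and interferon genes (1 of 16 rose) had adjusted p of 0.00698 and 0.0124, and adjusted p of 0.45 and 0.46 with an estimated correlation. Of 28 G2/M genes 3 fell, with Bub1 at -0.40, and the list was not called (adjusted p = 0.115). Adjusted over the list alone, 12 of 15 apoptosis genes, 10 of 14 cell cycle and feedback targets, 35 of 46 histones and 11 of 18 myeloid markers rose.

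The limma test called 2303 of 14637 genes for (-)-Nutlin, 1024 higher and 1279 lower, and 1129 higher and 819 lower with centred libraries. The count was 50 without the tumour term (no replicate block), 546 without T5 and 86 without T7. Between (+)-Nutlin and water, limma called 0 of 14637 genes, with 320 at an unadjusted p under 0.05, and 1 gene when uninfected groups were fitted separately. The difference for Cdkn1a was 0.25 (interval -0.54 to 1.04) and for Mdm2 0.10 (interval -0.12 to 0.33) on the log2 scale, so a change of Cdkn1a by up to 1.04 was not excluded. Replication histones (median -0.18) and ribosome biogenesis genes (median -0.07) were lower as lists with (+)-Nutlin (camera adjusted p = 8.82e-16 and 7.75e-08, and adjusted p = 0.376 and 0.22 with an estimated correlation), with 0 members called in either. G2/M (median -0.06), G1/S (-0.06) and B lineage genes (-0.09) were lower too (camera adjusted p = 9.3e-06, 2.98e-05 and 1.75e-05, and adjusted p = 0.343, 0.22 and 0.22 with an estimated correlation). Integrated stress response (median 0.18), immediate early (0.21) and p53 metabolism and stress genes (0.16) were higher (camera adjusted p = 0.000489, 0.0125 and 0.0466, and adjusted p = 0.0852, 0.575 and 0.22 with an estimated correlation). No member of these lists was called, and the fry adjusted p for the integrated stress response was 0.0208. Adjusted over that list alone 2 of 14 rose; Chac1 (1.53, interval 1.00 to 2.06, adjusted p = 0.109 over all genes) and Trib3 (1.02) were higher in 3 of 3 tumours. After quantile normalisation the ribosome biogenesis median was 0.02.

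**Figure D2:**
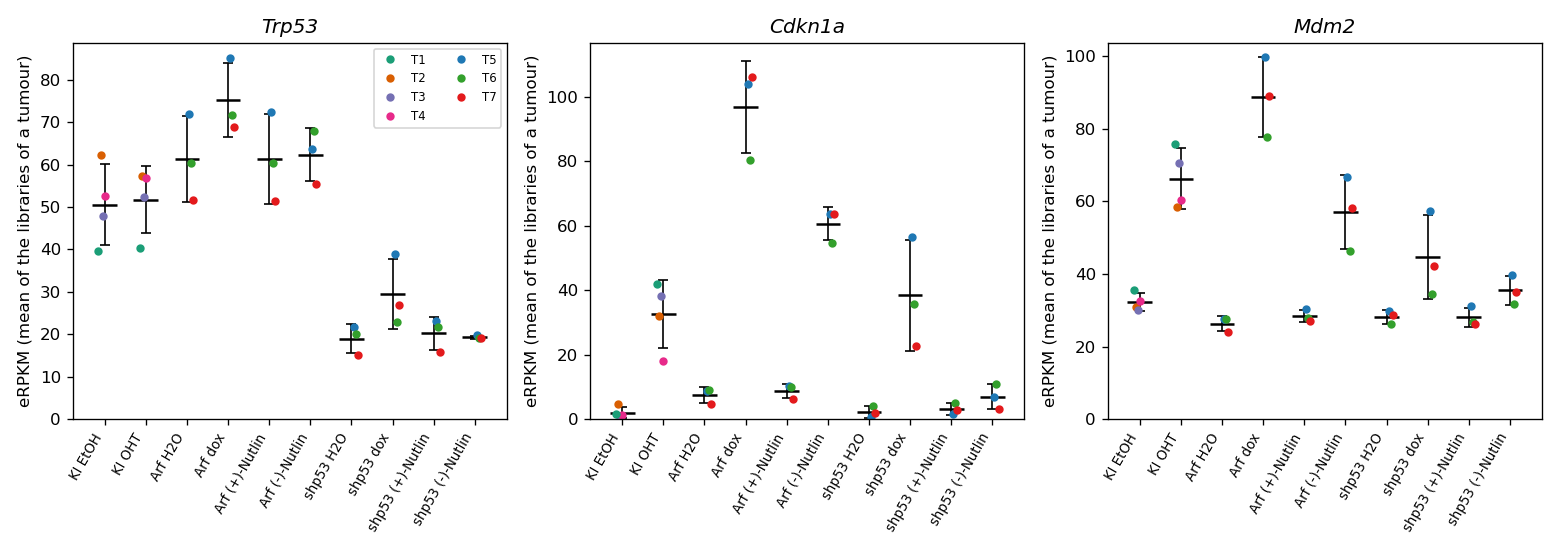
Trp53, Cdkn1a and Mdm2 (eRPKM) in the 10 groups; points are tumours, lines are group means and bars are SD. Cdkn1a reached 32.5, 96.8 and 60.7 eRPKM with OHT, doxorubicin and (-)-Nutlin.

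Genes called by OHT were largely called by the other treatments in the same direction. Among 11746 genes tested in each, 593 of 652 OHT rises were doxorubicin rises (142.1 for independent lists, Fisher exact odds ratio 46.6) and 449 were (-)-Nutlin rises (51.7 for independent lists, odds ratio 48.5). Of 302 OHT falls, 276 fell with doxorubicin (74.1 for independent lists, odds ratio 36) and 184 with (-)-Nutlin (32.9 for independent lists, odds ratio 14.7). These counts of shared falls changed with the filter, and for doxorubicin also with the pseudocount, as given below under the processing. All 3 treatments shared 440 rises, among them Cdkn1a, Mdm2 and Phlda3, and 178 falls. Doxorubicin and (-)-Nutlin shared 881 rises (197.2 for independent lists) and 874 falls (252.6 for independent lists). These treatments share no libraries, but the responses come from the same tumours and were tested with the same residual variance per gene. Genes of low variance can thus be called in both, so part of the excess over independent lists can arise from the shared fit.

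Doxorubicin and (-)-Nutlin responses differed in 108 genes. The activation antigen gene Cd69 (3.53), Tnfaip3 (3.52), Stx11 (2.78), the costimulatory receptor gene Cd40 (2.62) and Psd (2.53) rose more with doxorubicin, as did Mdm2 (0.73, SE 0.15, adjusted p = 0.0279). P2ry10 (-1.38), the B-cell antigen gene Ms4a1 (-1.36), Plac8 (-1.02), Abhd17b (-0.90) and C1d (-0.77) lay lower. In the NF-kB list 8 of 16 members were called, all higher with doxorubicin (adjusted p = 2e-08, and adjusted p = 0.183 with an estimated correlation), and in the p53 metabolism and stress list 4 of 19, the only list called with an estimated correlation (adjusted p = 0.0344). G2/M genes had a median of -0.28, with 0 of 28 called (adjusted p = 3.36e-09, and adjusted p = 0.183 with an estimated correlation). Cdkn1a differed by 0.90 (interval -0.21 to 2.02) and did not pass the test. Limma called 108 of 14637 genes, 92 higher and 16 lower, with 58 higher and 28 lower after centring. The count was 0 without the tumour term (no replicate block), without T5 and without T7, 238 with single libraries in a replicate block, 33 with T7 from rep2 libraries and 359 after quantile normalisation.

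With shp53, doxorubicin still raised Cdkn1a, by log2 3.93 (SE 0.37, adjusted p = 5.88e-06) from 2.27 ± 1.79 to 38.4 ± 17.1 eRPKM (SD, n = 3), and Mdm2 by log2 0.63 (SE 0.11, adjusted p = 0.00208). Cdkn1a rose by log2 5.59, 2.95 and 3.26 in T5, T6 and T7, and its SE comes from the residual variance over all 8 groups. Trp53 itself rose by log2 0.60 (SE 0.12, adjusted p = 0.00695). The activation gene Cd83 (4.90), Tnfaip3 (3.80), Stx11 (3.65) and Phlda3 (3.44) were the other largest rises. Thbd (-2.15), Rag2 (-2.06), Rag1 (-2.03), S1pr1 (-1.64) and Lrrn4 (-1.36) were the largest falls. Of 16 NF-kB targets 12 rose (adjusted p = 0.0198 with an estimated correlation), of 15 p53 apoptosis genes 9 rose (adjusted p = 0.00756) and of 14 cell cycle and feedback targets 8 rose (adjusted p = 0.0134), and of 28 G2/M genes 8 fell (adjusted p = 0.0466), each with an estimated correlation. Immediate early (12 of 19 rose, 1 fell) and integrated stress response genes (5 of 14 rose) were called too (camera adjusted p = 0.0466 for each with an estimated correlation). Of 27 G1/S genes 9 rose (camera adjusted p = 4.02e-06, and 0.114 with an estimated correlation). Of 19 B lineage genes 1 rose and 5 fell (camera adjusted p = 0.00129, and 0.238 with an estimated correlation). Adjusted over the list alone, 13 of 16 NF-kB targets and 12 of 15 apoptosis genes rose and 17 of 28 G2/M genes fell. Replication histones had a median of -0.30, with 0 of 46 called (adjusted p = 7.92e-13, and adjusted p = 0.299 with an estimated correlation). Limma called 944 of 14637 genes, 576 higher and 368 lower, and 516 higher and 608 lower after quantile normalisation. The count was 54 without the tumour term (no replicate block), 330 in a separate fit of shp53 groups, 55 without T5 and 345 without T7.

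With shp53, (-)-Nutlin raised the thiamine transporter gene Slc19a2 by log2 0.73 (SE 0.08, adjusted p = 0.000338), Ddias by 0.71, Ccng1 by 0.64 and Zfp958 by 0.52, and no other gene rose past the test. Cdkn1a was 1.00 higher (interval 0.21 to 1.79, adjusted p = 0.403) and Mdm2 0.33 higher (interval 0.11 to 0.55, adjusted p = 0.335). For Cdkn1a the responses were 1.859, 1.014 and 0.122 in T5, T6 and T7. The p53 apoptosis list (median 0.15, 0 of 15 called) and the cell cycle and feedback list (median 0.22, 1 of 14 called) were called as lists (adjusted p = 0.0186 and 0.0181 with an estimated correlation). Myeloid (median -0.36), T cell (-0.40) and stromal and endothelial markers (-0.46) were lower as lists (camera adjusted p = 0.0146, 0.00307 and 0.0198, and adjusted p = 0.607, 0.401 and 0.401 with an estimated correlation). None of their members was called, and T7 fell most, with medians of -0.43, -0.12 and -1.08 for myeloid and -0.25, -0.09 and -0.98 for T cell markers in T5, T6 and T7. The myeloid median was 0.06 after quantile normalisation. From (+)-Nutlin to (-)-Nutlin with shp53, the lower quartile of the library went from 1.149 to 0.186 eRPKM in T7. It went from 0.456 to 0.38 eRPKM in T5 and from 0.47 to 0.469 eRPKM in T6. A fall of these markers therefore cannot be told apart from a shift of low values between libraries. Limma called 18 genes, 4 higher and 14 lower, 8 of them RNAs under 200 bases. The count was 197 without the filter, 4 with the filter at 5 eRPKM, 0 in a separate fit, 11 with centring and 41 without T6.

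The difference between uninfected and shp53 responses was tested for each treatment. Under doxorubicin, Tnfsf4 (3.59), Fam131a (3.46), Zfp365 (2.89), Prrg4 (2.64) and Eppk1 (2.58) rose more without the hairpin, as did Mdm2 (1.09, SE 0.15, adjusted p = 0.00078). Myc differed by 0.49 (SE 0.15, adjusted p = 0.0424), but its own change passed the test neither without the hairpin (0.21) nor with the hairpin (-0.28). Cd83 (-3.48), Cxcr5 (-2.23), Tmem200b (-1.94), Grifin (-1.76) and Csrnp1 (-1.71) had lower responses without the hairpin. Tnfsf4 (0.129 eRPKM) and Fam131a (0.298 eRPKM) lay below the pseudocount in water without the hairpin. Low values lay higher with shp53 (median lower quartile 0.363 eRPKM, against 0 without), which can shrink log2 responses there. The size of these differences therefore depends on the floor. Cdkn1a differed by -0.25 (interval -1.36 to 0.86) and did not pass the test. Of 19 p53 metabolism and stress targets 11 rose more without the hairpin and 1 less (adjusted p = 0.00649 with an estimated correlation), while 0 of 16 NF-kB targets were called (median -0.03). Limma called 2068 of 14637 genes, 969 higher and 1099 lower, and 792 higher and 1363 lower with centring. The count was 3 without the tumour term (no replicate block), 68 without T5, 13 without T7 and 456 with T7 from rep2 libraries.

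Under (-)-Nutlin, the death receptor gene Fas (3.23), Zfp365 (3.19), Micall2 (3.16), Tnfsf4 (3.06) and Peli3 (2.55) rose more without the hairpin, as did Mdm2 (0.65, SE 0.15, adjusted p = 0.0353). Slc16a3 (-1.21), Slurp1 (-1.15), Zfp493 (-1.05), Msmo1 (-1.05) and Ankrd37 (-1.04) lay lower. Micall2 (0.282 eRPKM) and Tnfsf4 (0.179 eRPKM) lay below the pseudocount with (+)-Nutlin without the hairpin, so the same limit holds for them. Cdkn1a differed by 1.78 (interval 0.67 to 2.89, adjusted p = 0.0666). Of 14 cell cycle and feedback targets 4 were called, all higher (adjusted p = 1.51e-05, and adjusted p = 0.0907 with an estimated correlation). Limma called 425 genes, 247 higher and 178 lower, and 426 higher and 125 lower with centring. The count was 1 without the tumour term (no replicate block), 22 without T5, 13 without T7, 927 without T6 and 726 after quantile normalisation.

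In water, shp53 tumours differed from uninfected ones in Trp53 and in Cdkn1a (-1.65, SE 0.43, adjusted p = 0.0308). Gpr176 (2.59), Dux (2.47), Gabarapl1 (2.46), Epb4.1l4b (2.00) and Cd69 (1.92) were higher, and the chemokine gene Ccl7 (-3.15), Gpr132 (-3.12), Slc16a3 (-2.90), Ndufa4l2 (-2.84) and S100a8 (-2.75) were lower. Of 18 myeloid markers 4 were lower, with a median of -0.88 (adjusted p = 3.61e-05, and adjusted p = 0.592 with an estimated correlation), and of 46 replication histones 10 were higher (adjusted p = 7.62e-12, and adjusted p = 0.592 with an estimated correlation). T cell markers had a median of -0.58, with 1 of 14 lower, Lck at -1.84 (adjusted p = 0.00344, and adjusted p = 0.592 with an estimated correlation). Of 15 p53 apoptosis genes 3 were lower, with a median of -0.21 (adjusted p = 0.00344, and adjusted p = 0.555 with an estimated correlation), and of 14 integrated stress response genes 1 was higher (adjusted p = 0.011, and adjusted p = 0.592 with an estimated correlation). Limma called 933 genes, 359 higher and 574 lower, and 479 higher and 430 lower with centring. The count was 184 without the tumour term (no replicate block), 1501 with a pseudocount of 0.1, 569 with T7 from rep2 libraries, 568 without T5, 302 without T6 and 76 without T7. Uninfected and shp53 libraries labelled T7 differed in Ddx3y and Xist, so their pairing is open. For T5, Cdkn2a was lower by log2 -3.97 with shp53, and for T6 the correlation across infection was 0.18, against 0.489 for T5 and a median of -0.119 between tumours, so the pairing was less certain there too. Infection and hairpin cannot be separated in these labels. The treatments of a tumour counted as separate replicates in this comparison, so its SE and p-values, that of Trp53 included, can be too small.

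**Figure D3:**
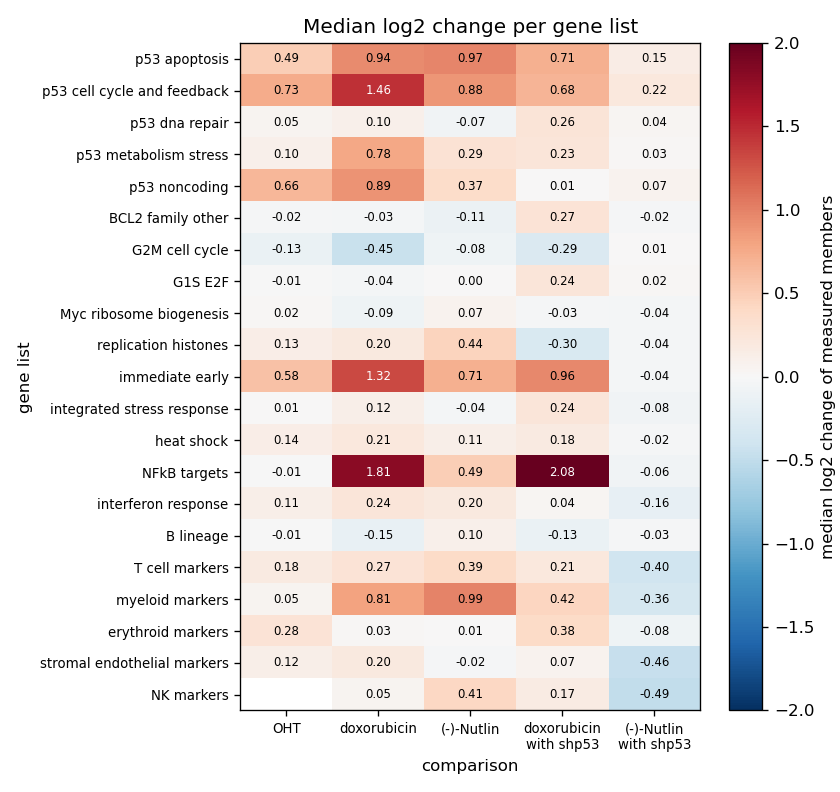
Median log2 change of the measured members of each gene list in 5 comparisons. NF-kB targets have medians of 1.81 and 2.08 with doxorubicin without and with shp53, and 0.49 with (-)-Nutlin.

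OHT and (-)-Nutlin responses, which differ in genotype, time and treatment at once, differed in few genes. Ak4 (1.56), Slc16a3 (1.26), Ankrd37 (1.07), P4ha1 (0.88) and Aacs (0.64) were relatively higher with OHT, and Fas (-1.64), Gdf15 (-1.46), Wfdc17 (-1.42), Msr1 (-1.28) and Fcer1g (-1.26) relatively higher with (-)-Nutlin. Mdm2 differed by 0.02 (interval -0.26 to 0.30) and Cdkn1a by 1.08 (interval 0.26 to 1.90, adjusted p = 0.359). Limma called 22 of 12272 genes, 7 higher and 15 lower. The count was 0 with all values as listed and after quantile normalisation, 1 with T7 from rep2 libraries, 10 with centring, 7 with a pseudocount of 0.1 and 9 without the filter. It was 9, 12, 4, 5 and 84 without T1, T3, T5, T7 and T6. Myeloid markers had a median of -0.565 (camera adjusted p = 6.22e-12, and adjusted p = 0.268 with an estimated correlation), with 1 of 16 called. Replication histones (median -0.306) and NF-kB targets (-0.468) were lower as lists too (camera adjusted p = 5.71e-12 and 5.22e-07). So were T cell, B lineage, interferon and p53 cell cycle and feedback genes (camera adjusted p = 0.0123, 0.0144, 0.0451 and 0.0451). No list was called with an estimated correlation.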

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

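All tests of explanations below, other than the counts of other splits of the samples, were chosen after the results were seen. The restriction of the OHT splits to those that part all tumour pairs was also chosen then.

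The library values of T1 ethanol rep1 stood far from its group of 8, with 14895 genes at 0 against 5983 to 7298 in the others (gap over range 0.852) and a highest value of 656.6 eRPKM against at most 307.0 (0.716). The T7 water rep1 library listed 7483 genes at 0 against 6525 to 6867 in the others of its group (0.643), and T3 OHT rep1 had a lower quartile of 0.012 eRPKM against 0.0 in the others (1.0). Cysltr1 with OHT was 6.92 eRPKM in T4 and 27.64 to 31.17 eRPKM in the other 3 tumours (0.977). Chance gives about 1 in 20 such results, and 40 sets of gene values and 21 sets of library values were tested.

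The doxorubicin response differed with shp53 in 2068 genes by the test of the difference, among them Tnfsf4 (3.59), Fam131a (3.46), Zfp365 (2.89), Prrg4 (2.64), Eppk1 (2.58), Mdm2 (1.09), Myc (0.49), Cd83 (-3.48), Cxcr5 (-2.23), Tmem200b (-1.94), Grifin (-1.76) and Csrnp1 (-1.71). The (-)-Nutlin response differed in 425 genes, among them Fas (3.23), Zfp365 (3.19), Micall2 (3.16), Tnfsf4 (3.06), Peli3 (2.55), Mdm2 (0.65), Slc16a3 (-1.21), Slurp1 (-1.15), Zfp493 (-1.05), Msmo1 (-1.05) and Ankrd37 (-1.04). The limit from low values given above for Tnfsf4, Fam131a and Micall2 holds here too.

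For OHT, 8 splits part all tumour pairs, too few for a share under 0.05. The real split called 955 genes, and the highest other of the 8 was 0, so the real split alone reached that count (1 of 8). Over all 32 splits that could be fitted the highest other was 31. With 10 splits for each comparison of T5 to T7, a share under 0.05 could not be reached. Counting the real split, the splits as large numbered 1, with a real count of 5710 and a highest other of 0 for doxorubicin, 2303 and 0 for (-)-Nutlin, 944 and 12 for doxorubicin with shp53, 2068 and 1 for the difference of doxorubicin responses, 425 and 0 for the difference of Nutlin responses, and 108 and 72 for doxorubicin against Nutlin. The splits as large numbered 2 for (-)-Nutlin with shp53 (18, highest other 192), 10 for (+)-Nutlin against water (0 and 0) and 3 for shp53 against uninfected (933 and 1048). For OHT against Nutlin, 2 of 35 splits, the real one included, gave as many genes as the real 22, so chance was not excluded, and the split of T1, T4, T6 and T7 against the others gave 650, which points to a structure among these tumours. The 192 genes of another split for (-)-Nutlin with shp53 point to one as well, and the cause was not tested for either. Other splits for shp53 against uninfected called 1048, 1037, 533 and 441 genes.

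The libraries labelled T7 differed in Ddx3y and Xist. A wrong label, 3 libraries from another tumour, predicts that they deviate unlike the other 5 over genes outside X and Y; the median correlation across the sets was -0.066, with 0.43 within the 3 and 0.738 within the 5. Uninfected libraries of different tumours had a median of -0.349, so the value lay above that of another tumour and below those within each set, and a mixture would give it as well. A mixture of cells of 2 tumours predicts that Xist relative to T7 rep2 and Ddx3y relative to T7 shp53 sum to about 1. The sums were 1.15, 1.39 and 1.13 (mean 1.22), which did not decide. No library of T1 to T6 held both RNAs at such levels. Xist was at most 5.45 eRPKM in T3, T4 and T6, and Ddx3y at most 0.03 eRPKM in T1 and T2, while T5 held little of either. These values argue against whole libraries swapped from T1 to T6. A wrong label with a tumour outside these, and a mixture, both stay open. No biological explanation was tested.

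Doxorubicin changed 944 genes despite shp53. For NF-kB targets, residual p53 acting no more strongly under doxorubicin than under (-)-Nutlin is argued against. Their doxorubicin response with shp53 exceeded their (-)-Nutlin response without it by 0.615 log2 or more in each tumour. Residual p53 acting more strongly under doxorubicin was not tested and stays open. A response of these targets that does not need p53 stays open: the median difference between uninfected and shp53 responses was -0.034, but it was -0.64, 0.57 and -0.53 in T5, T6 and T7. For 32 p53 list members, residual p53 acting alike under both treatments stays open, because the share of the response kept under doxorubicin exceeded that under (-)-Nutlin by 0.23, 0.24 and 0.011 in the 3 tumours.

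With (-)-Nutlin in uninfected tumours 8 of 18 myeloid markers were called higher, and 17 of 18 were higher in all 3 tumours by sign alone. As a list they were called with the preset correlation (adjusted p = 2.54e-07) but not with an estimated correlation (adjusted p = 0.248). A lower share of tumour cells would raise markers of other cell types alike, and it stays open. T cell markers had medians of 0.49, 0.25 and 0.60 in T5, T6 and T7, with 0 of 14 called (adjusted p = 0.00698, adjusted p = 0.45 with an estimated correlation, and 0.114 with fry). Over all members the myeloid median exceeded theirs by 0.21, 0.65 and 0.51 (SD 0.22), which in T5 is less than the SD. Over members with 2 eRPKM or more the gaps were 0.35, 0.76 and 0.62 (SD 0.21), above the SD in each tumour and against this explanation, so the outcome depended on the members taken. The gap of 14 myeloid to 4 erythroid and stromal markers was at least 1.04 log2 in each tumour. Pecam1, 1 of these 4, was 33.8 eRPKM with (+)-Nutlin, against 4.19 eRPKM for Sparc. Cd2 in the T cell list was 62.8 eRPKM in water. Which cells express them was not tested, so neither gap need measure other cell types alone. An effect of p53 activated by (-)-Nutlin stays open: the median difference between uninfected and shp53 responses was 1.38, with 1 of 18 members called. Part of that difference was a fall with shp53, with myeloid medians of -0.43, -0.12 and -1.08 in T5, T6 and T7, and T cell markers differed as well (median 0.94, adjusted p = 0.000457, and adjusted p = 0.359 with an estimated correlation). After quantile normalisation the myeloid median with shp53 was 0.06. In T7 with shp53 the lower quartile was 1.149 eRPKM with (+)-Nutlin and 0.186 eRPKM with (-)-Nutlin. The fall with shp53 can therefore not be told apart from a shift of low values between libraries. Myeloid levels with shp53 were 0.767 of those without at (+)-Nutlin, and in water the median difference was -0.88 with 4 of 18 lower. With T7 from rep2 libraries 7 of 18 were called in the difference of Nutlin responses. The most abundant of these markers with (-)-Nutlin were Lyz2 (49.4 eRPKM) and Cd68 (31.4 eRPKM), and a change in the myeloid cells themselves was not tested.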

How the results depend on the processing

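Quantile normalisation, all values as listed, T7 from rep2 libraries alone, and the reruns of overlaps and list tests were chosen after seeing the data; the other alternatives were fixed before. The cause of a change was not tested unless it is given. Apart from the alternative with all values as listed, at most 1 called gene per comparison changed sign under any alternative.

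With all values as listed, OHT called 1 gene (955 otherwise) and the comparison of OHT and Nutlin responses 0 (22 otherwise). This setting restored T1 ethanol rep1 and the X and Y values of T2 ethanol rep1 together, and the cause was not tested further. Of 954 OHT genes 780 kept their sign. In that setting Cybb was 0.339, Cysltr1 1.059 and Depdc1a 0.269 with OHT, reversed and not called.

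Without the tumour term (no replicate block), OHT called 28 genes, doxorubicin 2395 (5710 otherwise), (-)-Nutlin 50 (2303 otherwise), doxorubicin with shp53 54 (944 otherwise), the differences with shp53 3 for doxorubicin (2068 otherwise) and 1 for Nutlin (425 otherwise), doxorubicin against Nutlin 0 (108 otherwise) and shp53 against uninfected 184 (933 otherwise). With single libraries, 1 replicate block per tumour and replicate number, OHT called 2155 and doxorubicin against Nutlin 238. Separate fits of uninfected and shp53 groups gave 330 for doxorubicin with shp53, 0 for Nutlin with shp53 (18 otherwise), 174 for doxorubicin against Nutlin and 1 for (+)-Nutlin against water (0 otherwise).

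With no filter on low values, OHT called 43, Nutlin with shp53 197, the difference of Nutlin responses 252 and OHT against Nutlin 9. With the filter at 5 eRPKM, Nutlin with shp53 called 4, and shared falls numbered 476 for OHT and doxorubicin (276 otherwise) and 333 for OHT and Nutlin (184 otherwise). With a pseudocount of 0.1, shp53 against uninfected called 1501, OHT against Nutlin 7, and shared falls of OHT and doxorubicin numbered 181. Centring gave 11 for Nutlin with shp53 and 10 for OHT against Nutlin. Centring moved the median change of all genes from 0.054 to -0.089 for doxorubicin against Nutlin and from 0.051 to -0.065 for (+)-Nutlin against water. Quantile normalised libraries gave 726 for the difference of Nutlin responses, 359 for doxorubicin against Nutlin and 0 for OHT against Nutlin. With T7 uninfected from rep2 libraries, the difference of doxorubicin responses called 456, doxorubicin against Nutlin 33, shp53 against uninfected 569 and OHT against Nutlin 1.

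Leaving out 1 tumour gave 489 to 1564 for OHT, 2255 to 5701 for doxorubicin, 86 to 2444 for Nutlin, 55 to 1290 for doxorubicin with shp53, 16 to 41 for Nutlin with shp53, 13 to 2500 and 13 to 927 for the differences with shp53 of doxorubicin and Nutlin, 0 to 99 for doxorubicin against Nutlin, 76 to 568 for shp53 against uninfected and 4 to 84 for OHT against Nutlin. Fewer tumours lower the power of each test.

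Of the other count alternatives 130 stayed within 1.5 times the count given. Among named genes, 1240 alternatives kept direction and side of the threshold, 307 lost the call, 6 gained it and 3 reversed. Genes below the pseudocount, and the highest values, are limited by depth.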

Other observations

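Genes of sterol synthesis fell with (-)-Nutlin in uninfected tumours. The list was written after Msmo1, Hsd17b7, Mvd and Sc5d were seen among the falls, so its test is not independent evidence. Of 20 measured genes 18 fell and 0 rose, with a median of -0.57 log2, among them Msmo1 (-1.23), Mvd (-0.95), Lss (-0.88), Fdft1 (-0.72) and Sqle (-0.68). Without the genes that prompted the list, 14 of 16 fell, with a median of -0.47 (camera p = 0.00875 with an estimated correlation). The median was -0.55 with centred libraries, -0.57 after quantile normalisation and -0.70 with T7 from rep2 libraries. With doxorubicin 10 of 20 fell and 1 rose (camera p = 0.209 with an estimated correlation), and with OHT 3 fell. With shp53 0 were called for either treatment, with a median of 0.05 for doxorubicin and -0.138 for (-)-Nutlin. The latter had a camera p of 0.000124 with the preset correlation and 0.174 with an estimated correlation. After quantile normalisation the camera p with an estimated correlation was 0.0445, so a smaller fall with (-)-Nutlin and shp53 was not excluded.

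Genes of hypoxia and glycolysis, a list also written after Ak4, Slc16a3, Ankrd37 and P4ha1 were seen, fell in 9 of 20 cases with (-)-Nutlin, among them Ak4 (-1.39), Slc16a3 (-1.08), Slc2a1 (-0.63) and Hk2 (-0.49), while Ldha (0.18) and Pgk1 (0.14) were not called. Without the genes that prompted the list 5 of 16 fell, and the list did not pass the test (p = 0.152 with an estimated correlation). With doxorubicin 6 of 20 of the whole list fell and 1 rose (camera p = 0.145 with an estimated correlation), and with OHT 1 of 19 rose. With shp53 1 of 20 rose with doxorubicin, and 0 were called with (-)-Nutlin.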
